A study of Homo sapiens with 8 samples.

How the data were processed

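RNA was measured in Kelly, an established human neuroblastoma cell line, after staining of the cells with a fluorescent antibody to the ganglioside GD2 and sorting by flow cytometry into a GD2-low and a GD2-high fraction. Each fraction has 4 libraries, numbered 1 to 4 in the labels. Per the labels' protocols, RNA was extracted with a column kit and a commercial provider prepared the libraries and sequenced them as paired-end reads. Nothing in the labels says that the replicates came from separate cultures or sorts, so p-values measure only the spread between these samples, which may be technical.

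The deposited values are a normalised signal per gene: read counts divided by 1 factor per library. This was read from the values, since each value was a whole multiple of the smallest value above 0 in its library (100% of values within 0.001 reads). The factors differed by at most 0.561% from median-of-ratios factors recomputed from the recovered reads. Per the submitters' processing notes, Trimmomatic, FastQC, STAR, featureCounts, DESeq2 and R 4.0.3 were used with the GRCh38 (hg38) genome, with no role or order stated. The annotation, the strand setting and any filter are not given in the sources used here. Without a stated strand setting, it is not known whether reads from a gene and an overlapping antisense gene were separated. Each library listed the same 28281 gene symbols, of which 5926 were at 0 in all 8 libraries. Among the tested symbols, 133 shared all 8 values with another symbol, as near-identical gene copies do, and these are not independent measurements.

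Taking the smallest value as 1 read, the recovered libraries held between 11.0 and 24.1 M (1e6) assigned reads. Symbols of ribosomal RNA took 14.5% to 21.3% of them. No molecular identifiers are mentioned in the sources used here, so counting intervals cover counting error only. No pair of libraries within a group had counts that agree within sampling noise, so none were merged. Library preparations of 1 sample can also differ by more than sampling noise, so this does not show that the samples were separate.

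The test planned before the data were examined was edgeR's quasi-likelihood test for count tables, with limma named as the test for normalised values. Because the deposited signal values are normalised, limma 3.58.1 (trend and robust variance, R 4.3.3) on log2(value + 1) was used, with GD2-low relative to GD2-high and no covariate. Fold changes are on this log2(value + 1) scale, which understates the change of low genes. A gene was tested where edgeR's filterByExpr (minimum count 10, minimum total 15) kept its recovered reads, which left 14858 genes. P-values were adjusted by the Benjamini-Hochberg method over the tested genes with a threshold of 0.05. The procedure was tested on simulated libraries with 200 changed genes among 14858. It recovered 43.3% of genes changed 1.5-fold, 76.1% of those changed 2-fold and 93.9% of those changed 4-fold, and it called 12 of 14658 unchanged genes, 7.79% of its calls. The simulated libraries were drawn independently, without the split of the replicates into sets described below, so these shares may differ in the real data.

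The genes named were fixed by rule before the data were examined. Apart from some genes that are not reported here, they are the ganglioside enzymes ST8SIA1, B4GALNT1, ST3GAL5, UGCG, ST8SIA5 and B3GALT4, the adrenergic genes PHOX2A, HAND2, GATA3, ISL1, DBH, TH, MYCN and ALK, the mesenchymal genes PRRX1, VIM, FN1, CD44, YAP1, SNAI2 and TWIST1, and EZH2. To these the rule adds the 10 called genes with the largest change in each direction among those with a mean of at least 1 CPM, no overlap between the groups and a symbol outside the classes of unnamed loci, long intergenic, antisense and small RNAs. From each list it adds up to 4 members with the smallest p and the called members that go against the others.

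Before the data were examined, 36 gene lists were written from textbook knowledge. They cover ganglioside synthesis, ganglioside breakdown, adrenergic core regulators, noradrenergic and chromaffin products, mesenchymal regulators, mesenchymal products, collagens and matrix, YAP and TAZ targets, TGF-beta response, Notch pathway, immediate early response, heat shock, integrated stress and amino acid response, unfolded protein response, hypoxia and glycolysis, cholesterol synthesis, S phase, G2 and mitosis, replication-dependent histones, MYC and ribosome biogenesis, cytosolic ribosomal proteins, mitochondrially encoded genes, nuclear respiratory chain, interferon response, antigen presentation, polycomb complexes, p53 targets, neuronal differentiation, axon guidance and adhesion, Schwann and neural crest, retinoic acid response, surface immunotherapy targets and immune ligands, lysosome and autophagy, and markers of leukocytes, epithelium and endothelium. Lists with at least 5 tested members (33) were tested with limma's camera, which compares the members with all other genes, at a preset inter-gene correlation of 0.01 and adjusted over lists. The mitochondrially encoded genes were not analysed here. Camera ran on log2(value + 1) in place of the planned log2 CPM. The fry test, run beside it, asks whether a list's genes move on balance one way, and its mixed form whether they change in either direction. Neither compares the list with other genes. Members called are counted over all genes tested and, separately, adjusted over the list alone.

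Positions came from RefSeq genes on GRCh38.p14, matched by symbol for 95.7% of symbols and giving a chromosome for 14369 tested genes. Sets of at least 50 genes were tested per chromosome, not per arm, since no cytobands were used. After the fold changes had been seen along the chromosomes, 12587 protein-coding genes were put in order and a running median over 31 genes was taken. A run is a stretch of genes whose running median passed 0.298 on the log2 scale in either direction, a level that the largest running median passed in 5% of 1000 shuffled gene orders. Stretches of one direction at most 31 genes apart were joined. GC content and length of the longest transcript, a coding one where a gene had any, came from GENCODE release 29 and were known for 94.4% of tested genes.

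Whether the replicate numbers pair the samples was checked from the correlation of deviations from the group means. Libraries with the same number correlated at 0.277 to 0.375, above the 0.1 set in advance for each of the 4 pairs. Libraries with other numbers of the same set, replicates 1 and 2 or replicates 3 and 4, correlated as much (0.304 to 0.351), and those of different sets at -0.369 to -0.277. The pairing thus comes from the data and separates 2 sets of replicates. The labels give no batch, so the sets are treated as a technical split found in the data, and values within each set are given for part of the genes and lists.

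Alternatives fixed in advance were edgeR 4.0.16 with other scalings on the recovered reads, DESeq2 1.42.0, limma voom, edgeR's glmTreat against a 1.2-fold change, other filters, the replicate block and leaving out each library. Added after seeing the data were edgeR with TMM, other pseudocounts (0.5 and 5), limma with the replicate block, the set as a term, each set alone, analyses without the genes of the runs and the difference between the sets in camera with an estimated correlation. The count test on the recovered reads, edgeR with TMM, called 2292 genes.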

Results

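Kelly is a human neuroblastoma cell line. Its cells were sorted by surface GD2, a disialoganglioside that is the target of antibody therapy in neuroblastoma, and RNA of the GD2-low and GD2-high fractions was sequenced in 4 libraries each. The comparison asks which transcripts differ between cells of one line that carry little or much of the antigen, in a series concerned with changes of lineage state and the response to antibodies against GD2. The recovered libraries held 12.7 ± 0.812 M reads (M, 1e6) in the GD2-low group and 14.9 ± 6.13 M in the GD2-high group (mean ± SD, n = 4 each), with GD2-high replicate 2 at 24.1 M. At least 1 read was recovered for 18447 ± 258 symbols in GD2-low and 19097.5 ± 358 in GD2-high libraries. The first principal component (41.2% of the variance) separated the fractions and the second (27.4%) separated replicates 1 and 2 from replicates 3 and 4 in both. All changes are given for GD2-low relative to GD2-high cells, as log2 fold change ± SE.

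**Figure D1:**
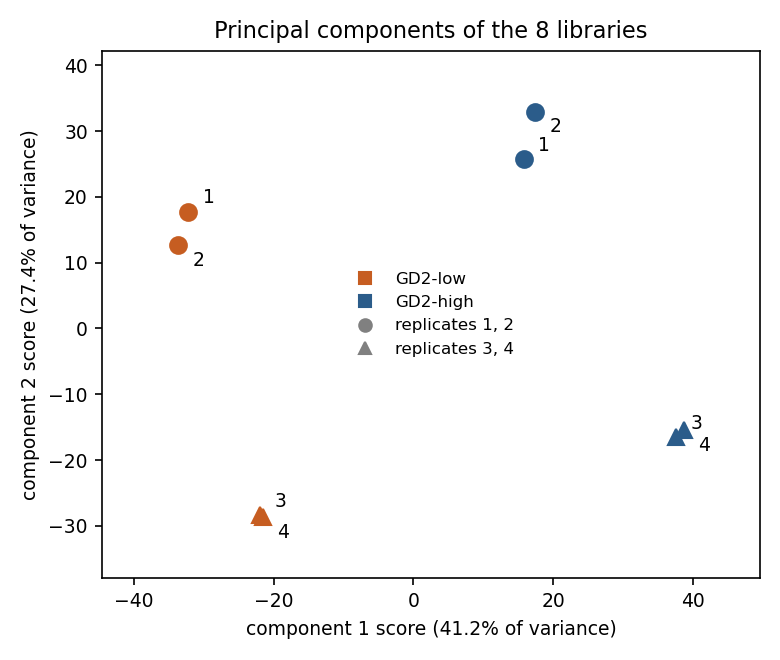
Scores of the 8 libraries on the first and second principal components of log2(value + 1) over 14858 genes, coloured by fraction, with circles for replicates 1 and 2 and triangles for replicates 3 and 4. Component 1 holds 41.2% and component 2 27.4% of the variance.

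ST8SIA1, which encodes GD3 synthase, the sialyltransferase that commits a ganglioside to the series containing GD2, was nearly absent from GD2-low cells. Its normalised value was 0.738 ± 0.941 in GD2-low and 108 ± 49.7 in GD2-high libraries (mean ± SD, n = 4 each), a change of -6.01 ± 0.49 (adjusted p = 1.5e-05). The 4 GD2-low libraries together held 3 reads of the gene and the 4 GD2-high libraries 441. The ratio of high to low was 125, with a 95% interval of 42.5 to 608 that covers counting error only. The gene lies on chromosome 12 from 22193391 to 22334707 (GRCh38.p14). It changed by -5.27 in replicates 1 and 2 and by -6.75 in replicates 3 and 4.

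The other enzymes of the pathway changed less than ST8SIA1 or did not pass. B4GALNT1, the GM2/GD2 synthase that makes GD2 from GD3 (chromosome 12, 57623409 to 57633201), stood at 544 ± 36.5 in GD2-low and 503 ± 53.9 in GD2-high cells, a difference within the spread between replicates (0.12 ± 0.09, adjusted p = 0.47). UGCG, the glucosylceramide synthase at the start of the pathway, rose by 0.52 ± 0.12 (adjusted p = 0.010), from 291 ± 27.6 to 420 ± 66.5, with changes of 0.68 and 0.36 in the first and second set of replicates. ST3GAL5, the GM3 synthase, had a value of -0.66 ± 0.26 that did not pass the test (adjusted p = 0.11), though it passed without GD2-high replicate 1 (adjusted p = 0.042), with the set as a term (0.043) and in replicates 3 and 4 (-0.87, 0.049, against -0.46 in replicates 1 and 2). ST8SIA5 did not pass either (-0.41 ± 0.41, adjusted p = 0.56), and B3GALT4, with 6 and 12 reads in the groups, was too low to test. Of 18 tested members of the ganglioside synthesis list, 3 rose and 3 fell, and 4 rose and 3 fell when adjusted over the list alone. The 3 that rose, UGCG, ST6GALNAC6 and B4GALT6 (0.50), all lie in runs of neighbouring genes that shifted together, described below. These runs, on chromosome 9 (UGCG and ST6GALNAC6) and chromosome 18 (B4GALT6), had medians of 0.55 and 0.35. The rises are thus not separate from those of their neighbours. ST6GALNAC6, a sialyltransferase of later steps, rose by 0.79 ± 0.12 (adjusted p = 9.7e-04) and GNE, the enzyme that starts sialic acid synthesis, changed by -0.40 ± 0.09 (adjusted p = 0.0081). The list as a whole did not stand apart from other genes (camera adjusted p = 0.67). Its median was 0.08 and its mean -0.25, and camera gave the direction up where fry, at an adjusted p of 0.97, gave down.

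**Figure D2:**
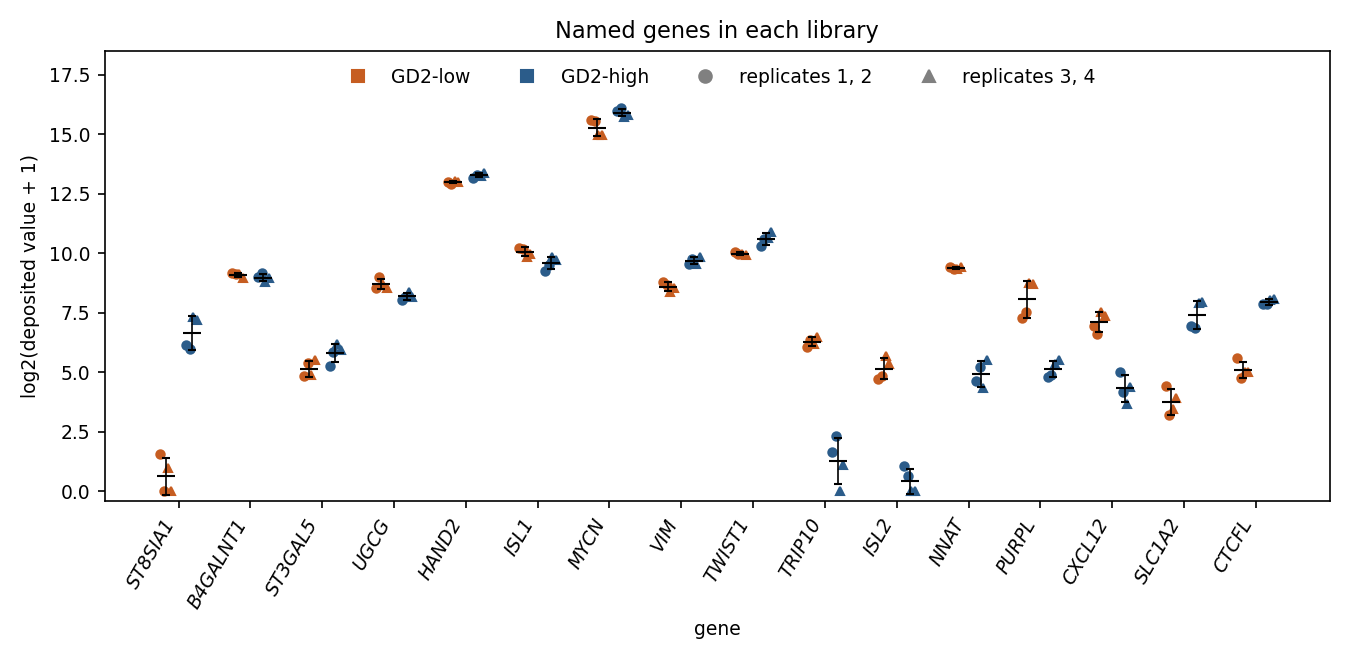
Values of 16 named genes in each library as log2(deposited value + 1), with GD2-low and GD2-high libraries side by side, circles for replicates 1 and 2, triangles for replicates 3 and 4, and bars for the mean ± SD (n = 4 each). ST8SIA1 lies near 0 in the GD2-low libraries, and B4GALNT1 differs by 0.12 ± 0.09.

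Beyond ST8SIA1, the transcripts with the largest changes had varied known roles. TRIP10, an adaptor of the GTPase CDC42, rose by 5.0 ± 0.47 (adjusted p = 2.8e-05), from 1.83 ± 1.68 to 77.2 ± 10.4. Its neighbour GPR108, which ends at 6737580 on chromosome 19 where TRIP10 begins at 6739680, rose by 3.30 ± 0.43. NNAT, an imprinted gene of neuronal cells, rose by 4.44 ± 0.22 (adjusted p = 4.5e-07), from 31.3 ± 11.7 to 664 ± 25.9 (chromosome 20, 37521250 to 37523690). ISL2, a LIM homeodomain factor of motor neuron development, had 137 reads in GD2-low and 2 in GD2-high libraries, a ratio of 80.6 with a 95% counting interval of 21.9 to 672. The metalloprotease gene ADAMTS9 (2.64 ± 0.20), the chemokine gene CXCL12 (2.79 ± 0.30) and the p53-induced noncoding RNA PURPL (2.92 ± 0.34) also rose, with adjusted p-values of 1.7e-05, 7.8e-05 and 2.2e-04. ZNF439 (3.30 ± 0.63) and the homeobox gene HOXD11 (2.97 ± 0.50) were also among the 10 largest increases.

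Among the transcripts that fell, CTCFL, the germline paralog of the chromatin factor CTCF, changed by -2.86 ± 0.18 (adjusted p = 1.8e-06), from 248 ± 20.9 to 34 ± 9.11 (chromosome 20, 57495965 to 57525652). The glutamate transporter gene SLC1A2 changed by -3.66 ± 0.33 (adjusted p = 2.3e-05) and CNTN4, an axonal adhesion molecule, by -3.85 ± 0.42 (adjusted p = 9.9e-05). PRSS50, a serine protease of the testis, changed by -4.38 ± 0.55, and HES7, a transcriptional repressor of the bHLH family, by -3.21 ± 0.37. TMEM196 (-3.77 ± 0.67), ANKRD20A19P (-3.68 ± 0.43), ARAP3 (-2.85 ± 0.61) and TMEM190 (-2.84 ± 0.69) complete the 10 largest decreases together with ST8SIA1. The call of TMEM190 (adjusted p = 0.022) was lost with edgeR (0.090), with edgeR and the replicate block (0.054) and with DESeq2 (0.11), and also without GD2-low replicate 3 (0.057) or GD2-high replicate 4 (0.060).

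Genes of the adrenergic identity of neuroblastoma cells moved both ways. INSM1, a zinc finger factor of sympathoadrenal development, rose by 1.18 ± 0.16 (adjusted p = 3.9e-04) and EYA1, a transcriptional coactivator, by 0.52 ± 0.11 (adjusted p = 0.0062). NPY, the neuropeptide of sympathetic neurons, rose by 1.88 ± 0.24 (adjusted p = 2.9e-04), whereas SLC18A2, the vesicular monoamine transporter, changed by -0.83 ± 0.11 (adjusted p = 3.5e-04) and the synaptic vesicle protein gene SYP by -0.32 ± 0.07 (adjusted p = 0.0091). Of 16 adrenergic core regulators, 3 rose and 3 fell, and 5 rose and 5 fell when adjusted over the list alone (median 0.13, camera adjusted p = 0.58, medians of 0.11 and 0.03 in the 2 sets). Of 18 noradrenergic and chromaffin products, 1 rose and 3 fell, with the same counts adjusted over the list alone (median 0.12, camera adjusted p = 0.67).

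MYCN, the oncogene amplified in this line (chromosome 2, 15940550 to 15947004), stood at 40509 ± 9917 in GD2-low and 61254 ± 6572 in GD2-high cells (-0.62 ± 0.17, adjusted p = 0.026), and its change was larger in replicates 3 and 4 (-0.81) than in replicates 1 and 2 (-0.44, adjusted p of the difference 0.0022). That call was lost without GD2-low replicate 3 (adjusted p = 0.084), GD2-low replicate 4 (0.082), GD2-high replicate 1 (0.051) or GD2-high replicate 2 (0.052). HAND2, an adrenergic transcription factor, changed by -0.29 ± 0.08 (adjusted p = 0.030), which was lost without GD2-low replicates 1 (0.053), 2 (0.094), 3 (0.064) or 4 (0.076) and without GD2-high replicates 3 (0.057) or 4 (0.089). Fits without 1 library had no term for the sets, which they leave unbalanced. With the replicate block in limma MYCN and HAND2 kept their calls. ISL1, a LIM homeodomain factor, rose by 0.48 ± 0.13 (adjusted p = 0.026), by 0.83 in replicates 1 and 2 against 0.12 in replicates 3 and 4 (adjusted p of the difference 0.0018). The ISL1 call was lost with the replicate block (adjusted p = 0.052) and without GD2-low replicates 1 (0.075) or 2 (0.083) or GD2-high replicates 1 (0.057) or 2 (0.053).

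Other adrenergic genes missed the threshold in the comparison of the groups, and 3 of them passed with the set as a term. PHOX2A, a homeodomain factor, had a value of 0.31 ± 0.17 (adjusted p = 0.25, 0.025 with the set as a term and 0.034 with the replicate block). GATA3 had -0.36 ± 0.13 (adjusted p = 0.094, 0.039 with the set as a term and 0.028 without GD2-low replicate 1) and differed between the sets, at -0.05 and -0.66 (adjusted p = 4.3e-04). With the replicate block in limma GATA3 did not pass. TH, the first enzyme of catecholamine synthesis, had -0.17 ± 0.15 (adjusted p = 0.51), with -0.42 and 0.08 in the sets (adjusted p of the difference 8.7e-04). DBH, which makes noradrenaline, did not pass over all libraries (0.23 ± 0.13, adjusted p = 0.27), though it passed with the set as a term (0.015) and, with the variance of all libraries, in each set (0.16, adjusted p = 0.047, and 0.31, 2.0e-04). On their own variance replicates 1 and 2 did not pass (adjusted p = 0.17), and DBH did not pass with the replicate block in limma. The receptor kinase gene ALK (0.10 ± 0.08, adjusted p = 0.46) did not pass.

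VIM, which encodes the intermediate filament vimentin, and TWIST1, a mesenchymal transcription factor, were both lower in GD2-low cells. VIM changed by -1.09 ± 0.11 (adjusted p = 3.7e-05), from 824 ± 88.3 to 388 ± 46.3 (chromosome 10, 17228241 to 17237593), and by -0.93 and -1.24 in the sets. TWIST1 changed by -0.63 ± 0.11 (adjusted p = 0.0021), from 1581 ± 266 to 1014 ± 34, and by -0.43 and -0.82 in the sets. In the other direction, TCF4 (0.64 ± 0.10, adjusted p = 0.0011), SMAD3 (0.52 ± 0.09, adjusted p = 0.0022), the glucocorticoid receptor gene NR3C1 (0.61 ± 0.14, adjusted p = 0.014) and the N-cadherin gene CDH2 (0.55 ± 0.08, adjusted p = 5.0e-04) rose. Of 16 tested mesenchymal regulators, 4 rose and 2 fell, and 5 rose and 4 fell when adjusted over the list alone (median 0.01, mean -7.5e-04, camera direction up with adjusted p = 0.67). Of 23 mesenchymal products, 3 rose and 2 fell, and 6 rose and 4 fell when adjusted over the list alone (median 0.11, camera adjusted p = 0.58).

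FN1, which encodes fibronectin, had a value of 0.43 ± 0.14 (adjusted p = 0.065, 0.0018 with the set as a term, 0.0067 with the replicate block, 0.047 with DESeq2, 0.013 without GD2-high replicate 3). CD44 had -0.21 ± 0.20 (adjusted p = 0.54), with opposite values of 0.38 and -0.80 in the sets (adjusted p of the difference 0.0011). PRRX1, YAP1 and SNAI2, regulators of the mesenchymal state, had too few reads to test, with 18, 25 and 25 reads in GD2-low and 47, 55 and 15 in GD2-high libraries. EZH2, the methyltransferase of polycomb repressive complex 2, rose by 0.30 ± 0.08 (adjusted p = 0.026), from 1876 ± 189 to 2308 ± 38.8. The EZH2 call was lost without GD2-low replicates 2 (0.066), 3 (0.066) or 4 (0.065) and without GD2-high replicates 3 (0.074) or 4 (0.078), but it held with the replicate block in limma.

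Across 14858 tested genes, 1016 were higher and 1208 lower in GD2-low cells, 2224 in all, of which 130 rose and 348 fell at least 2-fold. An unadjusted p under 0.05 was reached by 4260 genes. With the replicate block 3600 genes passed (1667 higher, 1933 lower), among them 2213 of the 2224. In replicates 1 and 2 alone, with the variance of all libraries, 2669 genes passed and in replicates 3 and 4 4106, and of 1767 genes that passed in both sets 1721 had the same sign. Fold changes of the 2 sets correlated at 0.628 across genes, which are not independent replicates, and 527 genes differed between the sets by a test of the difference. Among these are genes named here without values for each set elsewhere, with changes in replicates 1 and 2 and in replicates 3 and 4 of 0.47 and 1.01 for NUSAP1, 0.25 and 0.75 for DLGAP5, 0.63 and 1.32 for PLXNA2, 0.66 and 0.20 for FN1, -1.04 and -0.53 for VEGFA, -1.41 and -0.46 for PFKFB4, -0.54 and -1.04 for COL6A1, -0.76 and -1.30 for RPSA, -0.25 and -0.68 for RPLP2 and -0.24 and -0.80 for RPL10. Of the 2224 genes, 2095 had all libraries of one group above all of the other. Over all tested genes that share was 20.8%, where chance gives 2.86%.

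Lists of cell division genes stood higher than other genes in GD2-low cells by camera with its preset correlation, though not with an estimated one. Of 37 tested genes of G2 and mitosis, 13 rose and 0 fell, and 25 rose when adjusted over the list alone, with a median of 0.33 (camera adjusted p = 9.4e-10, but adjusted p = 0.80 with an estimated correlation). NUSAP1, a protein of the mitotic spindle, rose by 0.74 ± 0.13 (adjusted p = 0.0022), UBE2C, an enzyme of the anaphase-promoting complex, by 0.56 ± 0.10 (adjusted p = 0.0029), and DLGAP5, another spindle protein, by 0.50 ± 0.10 (adjusted p = 0.0056). The median was 0.13 in replicates 1 and 2 and 0.51 in replicates 3 and 4 (adjusted p of the difference 7.0e-24, and 0.014 with an estimated correlation). Of 36 S phase genes, 4 rose and 1 fell, and 2 rose and 1 fell when adjusted over the list alone. Their median was 0.14 (camera adjusted p = 0.0093), with adjusted p = 0.80 with an estimated correlation. It was 0.06 in replicates 1 and 2 (adjusted p = 0.14) and 0.25 in replicates 3 and 4 (adjusted p = 1.6e-06). The difference between the sets had adjusted p = 6.2e-06, which was lost at 0.087 with an estimated correlation. WDR76 (2.14 ± 0.19, adjusted p = 2.0e-05) and POLD3, a subunit of DNA polymerase delta (0.80 ± 0.11, adjusted p = 4.0e-04), rose, whereas the licensing factor gene CDT1 changed by -0.49 ± 0.08 (adjusted p = 0.0020). The S phase call was lost without GD2-low replicate 1 (median 0.08, adjusted p = 0.11), GD2-high replicate 3 (0.06, 0.11) or GD2-high replicate 4 (0.06, 0.14), and the median moved to 0.21 without GD2-low replicate 4 and to 0.23 without GD2-high replicate 2.

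Targets of p53 stood higher than other genes as well. Of 23 tested targets, 7 rose and 0 fell, and 10 rose when adjusted over the list alone, with a median of 0.27 (camera adjusted p = 2.6e-04) and medians of 0.19 and 0.28 in the sets. The call was lost at adjusted p = 0.56 with an estimated correlation, and fry, which asks whether the genes move on balance one way, gave an adjusted p of 0.0060. With the group alone in the model it was the 1 of the 7 called lists that fry called, and the other 6 had adjusted p-values of 0.11 to 0.32 by fry. With the set as a term fry gave the p53 targets an adjusted p of 0.0036. The other called lists then had 0.0036 to 0.033, save the ribosomal proteins (0.090). CDKN1A, the cyclin-dependent kinase inhibitor p21, rose by 1.08 ± 0.18 (adjusted p = 0.0027), from 512 ± 147 to 1056 ± 135. TP53INP1 rose by 1.05 ± 0.16 (adjusted p = 0.0010), ZMAT3, an RNA-binding protein, by 0.61 ± 0.09 (adjusted p = 6.2e-04) and the death receptor gene TNFRSF10B by 0.43 ± 0.07 (adjusted p = 0.0020).

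Some genes of the translation machinery fell in GD2-low cells, and the ribosomal protein list differed between the sets of replicates. Of 39 cytosolic ribosomal protein genes, 0 rose and 10 fell, and 1 rose and 21 fell when adjusted over the list alone (median -0.31, camera adjusted p = 1.4e-07, but adjusted p = 0.80 with an estimated correlation). The median was -0.04 in replicates 1 and 2 (adjusted p = 0.40) and -0.57 in replicates 3 and 4 (adjusted p = 3.2e-28), a difference with adjusted p = 6.8e-48 (0.044 with an estimated correlation). RPSA, the laminin-binding protein of the small subunit, changed by -1.03 ± 0.11 (adjusted p = 1.0e-04), RPLP2 by -0.46 ± 0.10 (adjusted p = 0.0089) and RPL10 by -0.52 ± 0.12 (adjusted p = 0.014). The one member higher by the count over the list alone was RPL35, named after its value was seen. Of 32 genes of MYC response and ribosome biogenesis, 0 rose and 3 fell, with the same counts adjusted over the list alone (median -0.11, camera adjusted p = 0.0026, adjusted p = 0.80 with an estimated correlation, -0.07 and -0.15 in the sets, and -0.07 without GD2-low replicate 4). The nucleolar proteins GNL3 (-0.72 ± 0.07, adjusted p = 6.7e-05), RRP9 (-0.99 ± 0.11, adjusted p = 1.0e-04) and NOP56 (-0.41 ± 0.07, adjusted p = 0.0028) were those that fell. GNL3, RRP9 and RPSA lie in a run of chromosome 3, described below, whose genes fell together (median -0.59).

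Some genes induced by low oxygen fell in GD2-low cells. Of 25 tested genes of hypoxia and glycolysis, 0 rose and 6 fell, and 9 fell when adjusted over the list alone, with a median of -0.18 (camera adjusted p = 0.0018, adjusted p = 0.80 with an estimated correlation). NDRG1 changed by -1.20 ± 0.15 (adjusted p = 2.7e-04), VEGFA, the vascular growth factor, by -0.78 ± 0.10 (adjusted p = 3.6e-04) and ENO2, the neuronal enolase, by -0.56 ± 0.08 (adjusted p = 5.5e-04). The median was -0.36 in replicates 1 and 2 and -0.04 in replicates 3 and 4 (adjusted p of the difference 3.1e-12, 0.041 with an estimated correlation), and it moved to -0.11 without GD2-high replicate 1 and to -0.28 without GD2-high replicate 3. Of 25 genes of the integrated stress and amino acid response, 1 rose and 6 fell, and 1 rose and 9 fell when adjusted over the list alone (median -0.19, camera adjusted p = 0.0090, adjusted p = 0.80 with an estimated correlation). The median was -0.29 in replicates 1 and 2 (adjusted p = 2.4e-07) and -0.16 in replicates 3 and 4 (adjusted p = 0.34). The difference between the sets had adjusted p = 4.3e-05, or 0.051 with an estimated correlation. CEBPB (-0.69 ± 0.11, adjusted p = 0.0014), the mitochondrial enzyme gene PCK2 (-0.59 ± 0.11, adjusted p = 0.0026) and the pseudokinase gene TRIB3 (-0.77 ± 0.14, adjusted p = 0.0027) fell, while WARS1, a tRNA synthetase gene, rose by 0.51 ± 0.10 (adjusted p = 0.0051). The call of this list, not that of WARS1, was lost without GD2-high replicate 1 (adjusted p = 0.087) or 2 (0.073).

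**Figure D3:**
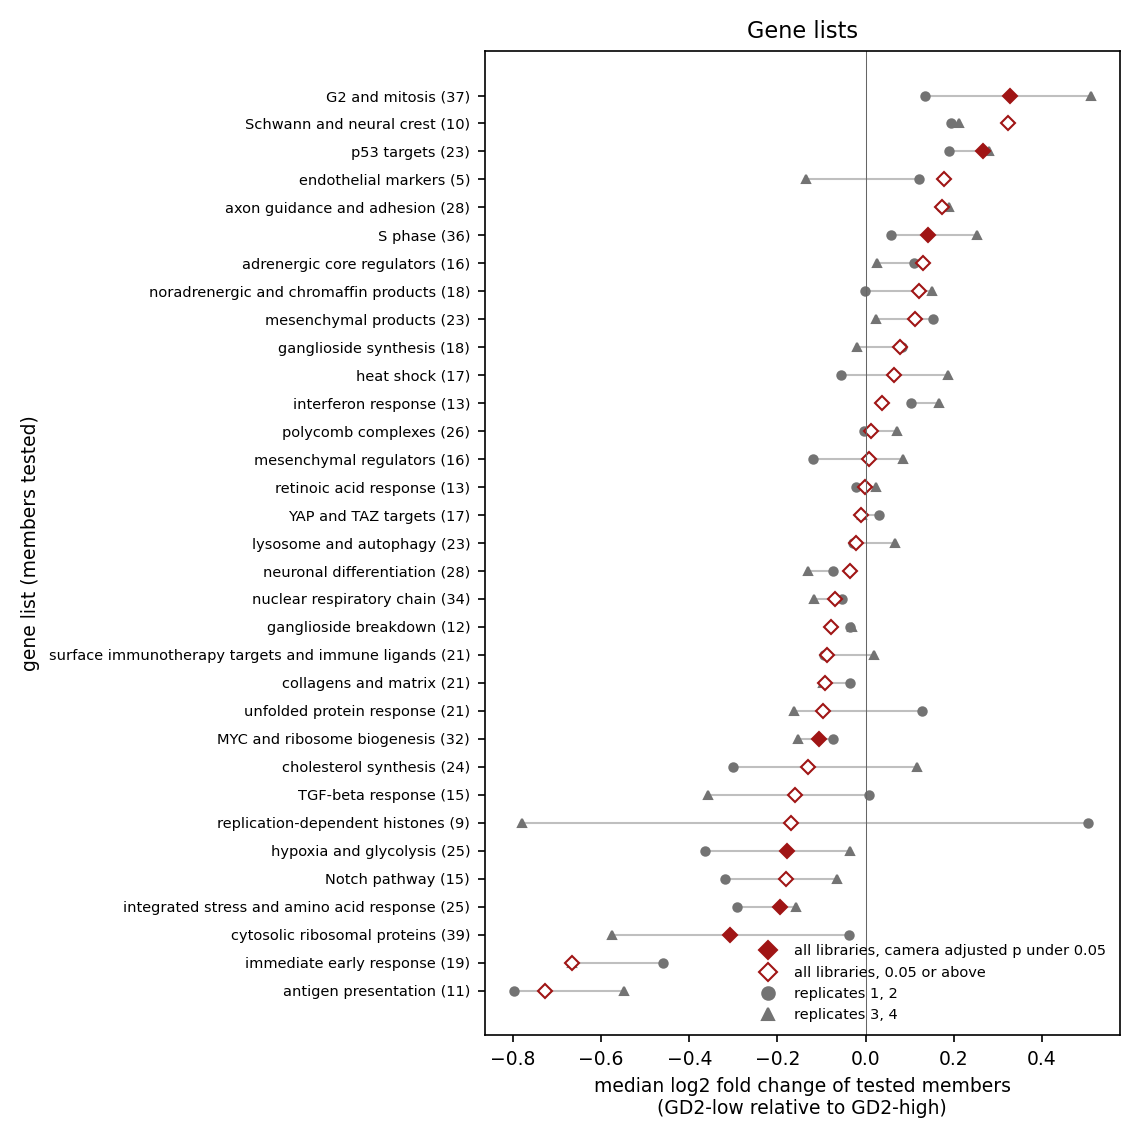
Median log2 fold change of the tested members of 33 gene lists, with diamonds for all 8 libraries (filled where the camera adjusted p is under 0.05, 7 lists), circles for replicates 1 and 2 and triangles for replicates 3 and 4. The ribosomal protein list lies at -0.04 in the first set and at -0.57 in the second.

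Several collagen genes fell although the matrix list was not called. COL11A1, a fibrillar collagen, changed by -2.09 ± 0.14 (adjusted p = 2.9e-06), COL5A1 by -1.69 ± 0.23 (adjusted p = 5.1e-04), COL6A3 by -0.80 ± 0.08 (adjusted p = 7.2e-05) and COL6A1 by -0.79 ± 0.11 (adjusted p = 5.3e-04). COL4A1, of the basement membrane, rose by 0.72 ± 0.20 (adjusted p = 0.032), a call that was lost without GD2-low replicates 1 (0.081), 2 (0.079) or 3 (0.080) or GD2-high replicates 3 (0.074) or 4 (0.089), but held with the replicate block in limma. Of 21 collagens and matrix genes, 3 rose and 6 fell, with the same counts adjusted over the list alone (median -0.09, camera adjusted p = 0.21). By fry the list moved on balance down (adjusted p = 0.0060), a test that does not compare it with other genes.

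Single genes of neuronal differentiation and of axon guidance changed in both directions, and neither list was called. GAP43, a growth cone protein, changed by -0.65 ± 0.07 (adjusted p = 6.2e-05), and the synaptic genes VAMP2 (-0.62 ± 0.09, adjusted p = 7.3e-04) and SNAP25 (-0.55 ± 0.09, adjusted p = 0.0017) fell, whereas the adhesion gene CNTN2 (0.48 ± 0.10, adjusted p = 0.0082) and the receptor kinase gene RET (0.76 ± 0.17, adjusted p = 0.010) rose. Of 28 neuronal differentiation genes, 2 rose and 6 fell, and 2 rose and 7 fell when adjusted over the list alone (median -0.03, camera adjusted p = 0.29, fry adjusted p = 0.012). Of 28 axon guidance and adhesion genes, 6 rose and 3 fell, and 9 rose and 4 fell when adjusted over the list alone (median 0.17, camera adjusted p = 0.21). The netrin receptor gene UNC5C (0.53 ± 0.08, adjusted p = 8.2e-04) and the semaphorin receptor gene PLXNA2 (0.97 ± 0.15, adjusted p = 9.7e-04) rose, and the cadherin gene CDH4 (-0.75 ± 0.12, adjusted p = 9.7e-04) and SEMA3E (-0.73 ± 0.12, adjusted p = 0.0019) fell. Of 10 Schwann and neural crest genes, 2 rose and 1 fell, and 2 rose and 2 fell when adjusted over the list alone (median 0.32, camera adjusted p = 0.39), with the transcription factor gene ETS1 at 0.84 ± 0.14 (adjusted p = 0.0019) and the endothelin receptor gene EDNRB at -0.73 ± 0.18 (adjusted p = 0.015).

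Genes of antigen presentation that changed were lower in GD2-low cells. CD74, the class II invariant chain, changed by -0.90 ± 0.18 (adjusted p = 0.0049) and PSMB10, an immunoproteasome subunit, by -0.78 ± 0.13 (adjusted p = 0.0020). Of 11 tested members 0 rose and 3 fell, and 4 fell when adjusted over the list alone (median -0.73, camera adjusted p = 0.11, which became 0.049 without GD2-high replicate 3 and 0.034 without GD2-high replicate 4). With an estimated correlation over all libraries the adjusted p was 0.80. The medians in the sets were -0.80 (adjusted p = 0.028) and -0.55 (adjusted p = 0.31), and a difference between the sets was not called (adjusted p = 0.34). Of 21 surface immunotherapy targets and immune ligands, 1 rose and 1 fell, and 0 rose and 1 fell when adjusted over the list alone (median -0.09, camera adjusted p = 0.58). GPC2, a glypican studied as a target in neuroblastoma, changed by -0.51 ± 0.12 (adjusted p = 0.013).

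Genes of signalling and chromatin lists changed singly, and none of these lists was called. In the retinoic acid response, ALDH1A3, a retinaldehyde dehydrogenase, rose by 2.32 ± 0.35 (adjusted p = 8.6e-04) and CRABP2, a retinoic acid carrier, changed by -1.49 ± 0.15 (adjusted p = 4.3e-05). Of its 13 tested members 3 rose and 3 fell, and 3 rose and 4 fell when adjusted over the list alone (median -0.0019, mean 0.07, camera direction down with adjusted p = 0.97). MFNG, a glycosyltransferase that modifies Notch receptors, changed by -1.76 ± 0.14 (adjusted p = 9.6e-06). Of 15 Notch pathway genes 0 rose and 2 fell, and 1 rose and 6 fell when adjusted over the list alone (median -0.18, camera adjusted p = 0.19, 0.80 with an estimated correlation, 0.038 without GD2-high replicate 3, medians of -0.32 and -0.06 in the sets). TGFBR1, a TGF-beta receptor, rose by 0.84 ± 0.10 (adjusted p = 1.3e-04) and the repressor gene SKIL by 0.39 ± 0.09 (adjusted p = 0.014). Of 15 TGF-beta response genes 2 rose and 1 fell, and 2 rose and 4 fell when adjusted over the list alone (median -0.16, camera adjusted p = 0.67), with medians of 0.01 and -0.36 in the sets (adjusted p of the difference 9.6e-04, lost at 0.28 with an estimated correlation). Of 17 YAP and TAZ targets 1 rose and 1 fell, with the same counts adjusted over the list alone (median -0.01, mean 0.03, camera direction up with adjusted p = 0.69).

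The polycomb gene PHF19 (0.75 ± 0.12, adjusted p = 0.0011) and the demethylase gene KDM2B (0.50 ± 0.10, adjusted p = 0.0046) rose, whereas PHF1 (-0.45 ± 0.10, adjusted p = 0.010) fell. Of 26 polycomb genes 4 rose and 2 fell, and 4 rose and 3 fell when adjusted over the list alone (median 0.01, mean -0.01, camera direction up with adjusted p = 0.67). OAS3, an antiviral enzyme gene, rose by 0.90 ± 0.21 (adjusted p = 0.014). Of 13 tested interferon response genes 3 rose and 1 fell, with the same counts adjusted over the list alone (median 0.04, camera adjusted p = 0.59). NEU4, a sialidase, changed by -0.52 ± 0.10 (adjusted p = 0.0048) and GLB1, the lysosomal beta-galactosidase, by -0.52 ± 0.11 (adjusted p = 0.0068). These were the 2 of 12 ganglioside breakdown genes that fell, with 0 that rose and the same counts adjusted over the list alone (median -0.08, camera adjusted p = 0.68). GLA, a lysosomal galactosidase, rose by 0.62 ± 0.09 (adjusted p = 6.7e-04), the 1 of 23 lysosome and autophagy genes called, also when adjusted over the list alone (median -0.02, mean 0.04, camera direction up with adjusted p = 0.67).

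Lists of metabolism and protein folding were not called over all libraries, and several differed between the sets. SEC61B, a subunit of the translocon, rose by 1.03 ± 0.12 (adjusted p = 1.9e-04) and MANF, a secreted stress factor, changed by -0.62 ± 0.11 (adjusted p = 0.0020), the 1 higher and 1 lower of 21 genes of the unfolded protein response, with the same counts adjusted over the list alone. That list had a median of -0.10 (camera adjusted p = 0.67), with 0.13 and -0.16 in the sets (adjusted p of the difference 3.9e-06, 0.041 with an estimated correlation). Of 24 cholesterol synthesis genes 0 rose and 1 fell, MVD (-0.53 ± 0.15, adjusted p = 0.038, lost without GD2-low replicates 1 (0.053), 2 (0.070), 3 (0.098) or 4 (0.093) or GD2-high replicates 1 (0.087) or 2 (0.078), but held with the replicate block in limma), and 0 rose and 0 fell when adjusted over the list alone (median -0.13, camera adjusted p = 0.29). The list passed without GD2-high replicate 3 (0.021) or 4 (0.017), though over all libraries its adjusted p was 0.80 with an estimated correlation. Its medians were -0.30 and 0.12 in the sets (adjusted p of the difference 3.7e-15, 0.014 with an estimated correlation). UQCRC1, a subunit of complex III, changed by -0.50 ± 0.11 (adjusted p = 0.0070) and ATP5MC1, a subunit of ATP synthase, by -0.47 ± 0.11 (adjusted p = 0.013). Of 34 nuclear genes of the respiratory chain 1 rose and 6 fell, and 2 rose and 7 fell when adjusted over the list alone (median -0.07, camera adjusted p = 0.16, 0.80 with an estimated correlation, 0.049 without GD2-low replicate 2 and 0.034 without GD2-high replicate 4). Of 9 replication-dependent histone genes 0 rose and 0 fell in limma, also when adjusted over the list alone (median -0.17, camera adjusted p = 0.67), with medians of 0.50 and -0.78 in the sets (adjusted p of the difference 6.2e-06, 0.041 with an estimated correlation).

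Genes that respond to handling and markers of other cells were examined because sorting stresses cells. Of 19 immediate early genes, 1 rose and 2 fell, with the same counts adjusted over the list alone, and the median was -0.67 (camera adjusted p = 0.11). The list passed with the replicate block (adjusted p = 5.7e-04) and without GD2-low replicate 1 (0.016), GD2-low replicate 2 (0.017), GD2-high replicate 3 (0.022) or GD2-high replicate 4 (0.028), and its medians were -0.46 and -0.66 in the sets. With an estimated correlation it did not pass, at adjusted p = 0.80, or 0.54 with the set as a term. NR4A3, an orphan nuclear receptor, rose by 0.94 ± 0.16 (adjusted p = 0.0017) and SOCS3 changed by -1.16 ± 0.26 (adjusted p = 0.0095). Of 17 heat shock genes 1 rose, also when adjusted over the list alone, which was BAG3 (0.65 ± 0.12, adjusted p = 0.0037), and the list had a median of 0.06 (camera adjusted p = 0.29), with -0.05 and 0.19 in the sets (adjusted p of the difference 3.3e-06, 0.041 with an estimated correlation).

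Few markers of other cell types were expressed. Of 20 leukocyte markers 4 could be tested and 0 changed, also when adjusted over the list alone. All 4 had values below 0, and CD4 (-1.57 ± 0.54, adjusted p = 0.072) passed with the replicate block (0.0065) and with the set as a term (0.0029). Of 20 epithelial markers 2 could be tested, of which KRT19 fell by 1.34 ± 0.28 on the log2 scale (adjusted p = 0.0070). That count was 1 lower when adjusted over the list alone, and both lists were too small for camera. Of 5 tested endothelial markers 0 rose and 2 fell, with the same counts adjusted over the list alone, EGFL7 by 1.78 ± 0.31 (adjusted p = 0.0022) and VWF by 1.19 ± 0.27 (adjusted p = 0.011). The median of that list was 0.18, its mean -0.38 and its camera direction down (adjusted p = 0.43). Symbols of ribosomal RNA took 18.2 ± 2.85% of the reads in GD2-low and 16.3 ± 1.25% in GD2-high libraries (mean ± SD, n = 4 each). In replicates 1 and 2 the shares were 14.5% and 19.1% in GD2-low against 18.2% and 15.6% in GD2-high libraries, and in replicates 3 and 4 they were 17.9% and 21.3% against 15.9% and 15.6%.

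Neighbouring genes moved together along several chromosomes. The tested genes of chromosomes 18 (median 0.15, adjusted p = 1.5e-05), 9 (0.11, 1.5e-05) and 12 (0.07, 0.014) were higher and those of chromosomes 3 (-0.12, 6.9e-05) and 17 (-0.06, 0.039) lower in GD2-low cells, 5 of 23 chromosomes by camera. With an estimated correlation chromosome 17 was lost (adjusted p = 0.12) and chromosomes 5 (0.031) and 7 (0.042) passed. Chromosome 17 was also lost without GD2-low replicate 3 (0.066), GD2-low replicate 4 (0.051) or GD2-high replicate 2 (0.080), and the number called was 11 without GD2-low replicate 1 and 8 without GD2-high replicate 3. Without the genes in the runs described next, 1 chromosome, 18, still passed (adjusted p = 4.4e-04).

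In the ordered genes, 13 runs with a shifted running median were found, 7 higher and 6 lower, which held 883 of 12587 protein-coding genes. The longest lay on chromosome 3 from 31.5 to 63.9 Mb, where 241 genes had a median of -0.59, 97.5% of them below 0 and 169 called lower, with -0.56 and -0.64 in the sets. On chromosome 9 from 98.1 to 131.5 Mb, 192 genes had a median of 0.55, with 127 called higher and 5 lower and medians of 0.49 and 0.63 in the sets. On chromosome 12 from 112.1 to 132.1 Mb, 116 genes had a median of 0.40. Chromosome 11 from 67.5 to 75.8 Mb (73 genes, 0.31), chromosome 4 from 16 to 25.9 Mb (23 genes, 0.45) and chromosome 18 from 23.5 to 35.3 Mb (28 genes, 0.35) were higher. A short run of chromosome 18 from 56.7 to 57.5 Mb (3 genes, 0.29) held 0 called genes, and it was the 1 run whose libraries overlapped between the groups (0.194 ± 0.184 in GD2-low against -0.184 ± 0.237 in GD2-high, mean ± SD of the median deviation from the mean of each gene, n = 4 each). Chromosome 7 from 2.23 to 23.5 Mb (72 genes, -0.31), chromosome 19 from 48.3 to 49.5 Mb (28 genes, -0.33) and from 54.2 to 55.4 Mb (17 genes, -0.41) and the X chromosome from 152.8 to 153.7 Mb (14 genes, -0.39) were lower. Counting genes of every kind, 960 tested genes lay in the runs (6.46% of all) and held 561 calls (25.2% of all).

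Several of the genes named above lie in these runs. Of 132 called genes named or among the listed members, 24 lie in a run, and 23 of them moved with its sign. On chromosome 3 these were PRSS50, GNL3, RRP9, RPSA, GLB1, PFKFB4, UQCRC1 and MANF. On chromosome 9 they were UGCG, ST6GALNAC6, TGFBR1, NR4A3, PHF19 and SEC61B. TWIST1 and TMEM196 lie in the run of chromosome 7, POLD3 in that of chromosome 11, OAS3, COX6A1 and KDM2B in that of chromosome 12, B4GALT6 and CDH2 in that of chromosome 18 and TMEM190 in one of chromosome 19. ARAP3, at the edge of a run of chromosome 5, went against it.

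**Figure D4:**
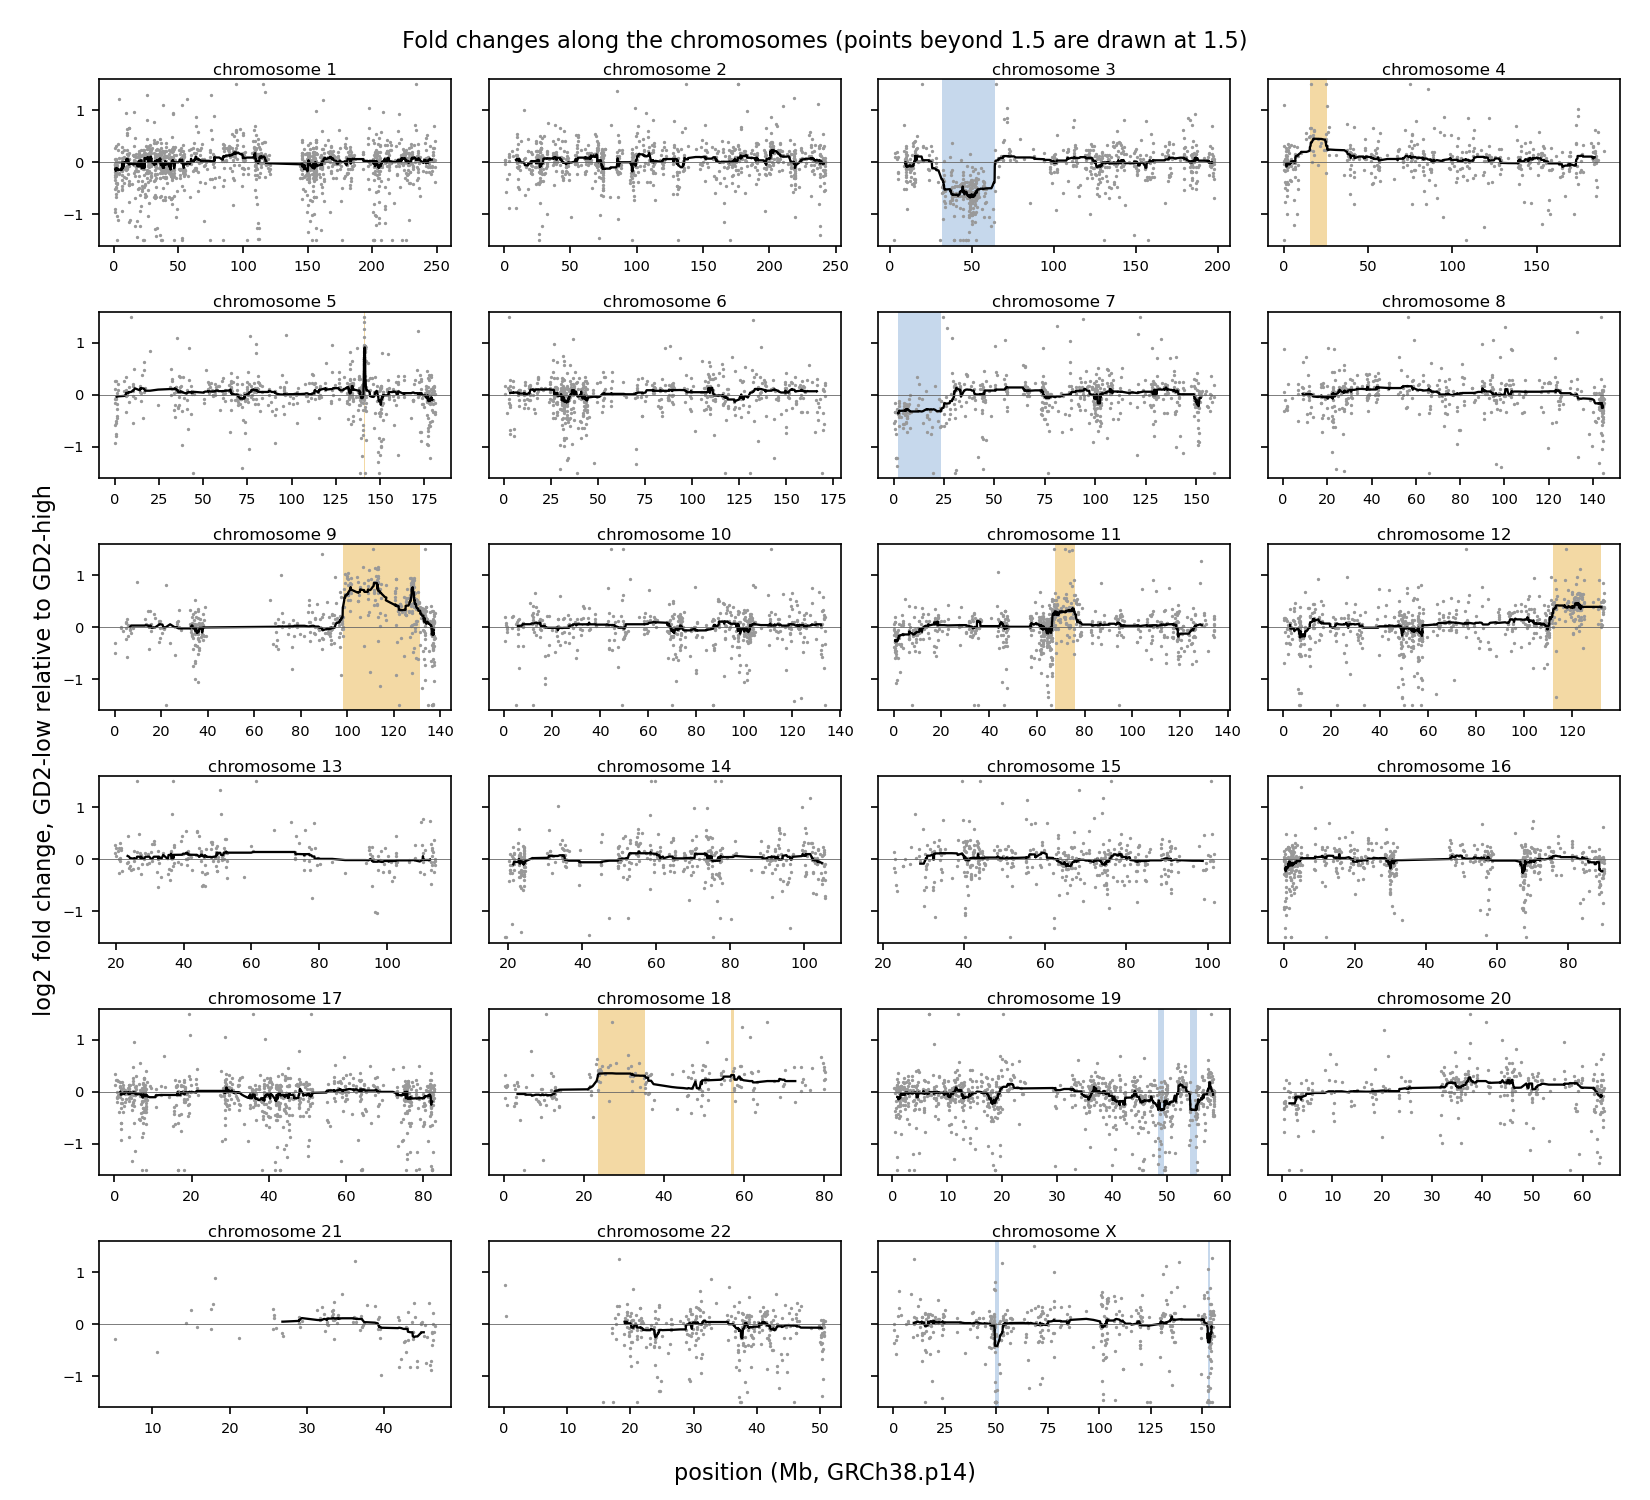
Log2 fold change of 12587 protein-coding genes (points, drawn at 1.5 where larger in size) and their running median over 31 genes (line) against position in Mb on each chromosome, with the 13 shifted runs shaded. The run of chromosome 3 spans 31.5 to 63.9 Mb with a median of -0.59, and that of chromosome 9 spans 98.1 to 131.5 Mb with a median of 0.55.

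The remaining runs held gene families. On chromosome 5 from 140.8 to 141.7 Mb, 57 genes had a median of 0.82, most of them clustered protocadherins, adhesion molecules of neurons. Of these families 14 of 15 tested PCDHA, 9 of 15 PCDHB and 21 of 21 PCDHG genes rose, with medians of 0.68, 0.83 and 0.91. On the X chromosome from 49.2 to 51.5 Mb, 19 genes had a median of -1.29, and all 21 tested symbols of the cancer-testis antigen family GAGE fell (median -1.95), though only 12 of these have distinct values. Of 10 MAGEA symbols 1 rose and 5 fell (median -0.52), and of 3 CSAG symbols 2 fell (median -1.27), as did the 1 PAGE symbol. Both XAGE symbols, which share their values, rose (1.18), and of 3 CTAG symbols 0 rose and 1 fell (median 1.28). Reads shared between members of these families were not separated, so single members are uncertain and counts of members may not be counts of independent measurements. The 21 PCDHG genes, for example, all changed by 0.82 to 0.94. The families were chosen after their values were seen.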

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

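Of the tests in this part, those on the order of the genes, on the difference between the pairs of replicates, on the sign of the genes of a run, on copy number, on the place of the mitotic genes and on the region around the protocadherin clusters were chosen only after the result was seen.

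In 20 of 366 groups of 4 values, each from the libraries of 1 fraction, 1 library lay far from the other three by Dixon's ratio of its gap to the whole range (above its 95% critical value). For independent values of 1 normal population chance flags about 1 in 20 groups, here 18.3. The groups share the same libraries, and the libraries fall into 2 sets, so this number is not a firm expectation and no conclusion is drawn from it. Among GD2-high libraries the ratio was 0.896 for GATA3 (replicate 4 at 11.91 on the log2 scale against 11.75 to 11.77), 0.878 for HOXD11 (replicate 4), 0.949 for GNE (replicate 4), 0.842 for SYP (replicate 2), 0.941 for MFNG (replicate 1), 0.872 for IFI35 (replicate 1) and 0.900 for CLDN5 (replicate 1). Among GD2-low libraries it was 0.874 for HES7 (replicate 3), 0.837 for TMEM190 (replicate 4 at 6.48 against 2.79 to 3.39), 0.848 for NEU4 (replicate 2), 0.932 for SKIL (replicate 1), 0.875 for HES6 (replicate 3), 0.943 for HEY1 (replicate 1), 0.845 for CDT1 (replicate 1), 0.865 for SNAP25 (replicate 1), 0.837 for CD68 (replicate 1) and 0.855 for VWF (replicate 4). Of the library measures of the GD2-high group, total reads gave 0.884 (replicate 2 at 24.1 M reads, 1e6 each, against 11.03 to 12.5), the percent of reads under ribosomal RNA symbols 0.884 (replicate 1 at 18.2 against 15.6 to 15.9) and the percent in the 10 highest symbols 0.953 (replicate 1 at 15.8 against 12.8 to 12.9).

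Runs of neighbouring genes shifted together, the longest on chromosomes 3, 9 and 12. Of 1000 shuffled gene orders 0 held as many genes in runs (at most 11 genes), though the threshold itself came from such orders. This argues against a random order of the genes, but it does not tie the runs to the fractions. Other splits of the libraries also held runs above their own thresholds, with a median of 208.5 genes. GC content and transcript length left 97.0% of the shift of the median run, though 1 run of chromosome 19 kept 32.5% and the other 55.4%. All runs found in replicates 1 and 2 (12, or 100%) held in replicates 3 and 4, which argues against a difference between the pairs of replicates, though not for the runs of chromosome 19, which replicates 1 and 2 alone did not show (medians of -0.24 and -0.29 there against -0.39 and -0.53). Of the genes of the median run found in replicates 1 and 2, 89.4% had its sign in replicates 3 and 4, which argues against a few strongly regulated genes in such a run. This share ignores the size of the shifts. Uncalled genes, which have smaller changes by selection, kept 57.1% of the shift in the median run. In the runs of chromosome 5 and of X from 49.2 Mb they had medians of 0.12 and -0.22, against 0.82 and -1.29 for all genes, so the share does not settle the question there. A copy number difference between subclones that differ in GD2 may underlie the runs. It cannot be told apart from regional regulation here, since DNA was not analysed. Shifts of genes below and above the median expression of their run differed by 0.162 in the median run, that of chromosome 11. This lies between the 0.15 and 0.3 set as bounds, but the median joins unlike runs. The difference was under 0.15 in the runs of chromosomes 3 (0.067), 4 (0.088), 7 (0.021), 9 (0.053) and 12 (0.012). The longer run of chromosome 18 (0.057) was under 0.15 too. It was 0.222 on chromosome 5, 0.305 in the short run of chromosome 18, 0.52 and 0.281 on chromosome 19 and 1.31 and 0.329 on X. Values under 0.15 met the bound set for copy number, but they do not exclude regional regulation.

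The median of the ribosomal protein list was lower and that of the mitotic list higher in GD2-low cells chiefly in replicates 3 and 4. The medians were -0.57 and 0.51 there against -0.04 and 0.13 in replicates 1 and 2. Over all libraries 10 of 39 ribosomal genes fell and 13 of 37 mitotic genes rose. With an estimated correlation camera called neither list (adjusted p = 0.80 each), though it called the differences between the sets (0.044 and 0.014). A correction for GC content and transcript length left at least 84.8% of each list's median in replicates 3 and 4, which argues against that trend as the whole cause. Genes in the shifted runs do not account for it either, since 0 of the 37 mitotic genes lie there and the ribosomal difference kept 100% of its size without the 6 of 39 that do. The share of ribosomal RNA reads was higher in GD2-low than in GD2-high libraries in replicates 3 and 4 (17.9% and 21.3% against 15.9% and 15.6%) and overlapped in replicates 1 and 2 (14.5% and 19.1% against 18.2% and 15.6%), so a difference in library preparation stays open, as does one in growth or handling, and neither was tested. No biological explanation was tested.

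Most protocadherin genes of chromosome 5 rose, with 14 of 15 PCDHA, 9 of 15 PCDHB and 21 of 21 PCDHG genes called higher. The PCDHB median was 0.83, with members from -0.096 to 1.58. The 38 flanking genes had a median of 7.3e-04, which is 0.0874% of the PCDHB median, so the copy number of the surrounding region is argued against. Changes of the PCDHG genes lay only between 0.82 and 0.94 and those of PCDHA between 0.40 and 0.81. Members with such similar changes may share reads, so the counts for PCDHA and PCDHG may not be counts of independent measurements. The same holds for their part in the run of chromosome 5. Reads shared between family members were not separated by any test. Regulation of the clusters stays open and may be a biological difference between the fractions.

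The replicate numbers met the rule for pairing, though libraries with other numbers of the same set correlated as much (0.304 to 0.351). Each result was compared across the 35 splits of the 8 libraries into 4 and 4, and across the 8 of these that part all pairs, the real split counted in both. The 8 are too few for a share under 0.05, and the 35 ignore the pairing, so neither can exclude chance. The shares among the 35 are given against the bound set in advance. For the number of called genes that bound was met: 1 of 35 splits, the real one, gave as many (2224), the highest other was 1072, which is the split by sets of replicates, and the others that part all pairs gave 0 in limma (with 57 to 1065 genes at an unadjusted p under 0.05). The real split thus stood apart from the others, though with the pairing kept its share is 1 of 8. For genes in runs the share set in advance was met, with 1 of 35 splits, but the highest other came close (898 against 879 with thresholds set for each split, and 708 among those that part all pairs). Each of these thresholds came from only 100 shuffled orders, and with 1000 the real split itself held 883. The rank is thus not secure, and chance is not excluded. At the threshold of the real split the values were 883 and 356. For gene lists chance cannot be excluded: 16 of 35 splits gave as many as the real 7, the highest 12, and 3 of the 8 that part all pairs did, the highest other of these 9. For chromosomes chance cannot be excluded either: 4 of 35 splits gave as many as the real 5, the highest 9, and 2 of the 8 that part all pairs did.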

How the results depend on the processing

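Of the settings in this part, edgeR with TMM factors, limma with the replicate block, the set as a term, each set alone, other pseudocounts, the analyses without the genes of the runs, the difference between the sets with an estimated correlation and the chromosomes without 1 library were chosen only after the result was seen. Among single genes and lists, 4672 values kept their direction and their side of the threshold, 173 came to pass, 252 no longer passed and 41 reversed. Of the counts, 158 stayed within 1.5 times the value reported and 24 moved. In simulated libraries 43.3% of genes changed 1.5-fold were recovered, so changes of this size can be missed, and the part that depth has in this was not tested.

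The count of 2224 genes became 983 (419 higher, 564 lower) with glmTreat, which asks for more than a 1.2-fold change, and 1435 (592 higher) without the genes of the runs, where fewer genes were tested. With replicates 3 and 4 only it was 4801 (2327 higher, 2474 lower, at least 2-fold 228 and 533); the cause was not tested. Leaving out 1 library gave 1598 to 2223 genes.

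The replicate block raised the count to 3600 (1667 higher, 1933 lower) with limma and 3608 (1706 and 1902) with edgeR, and the set as a term to 4281 (2011 and 2270), since these remove the difference between sets from the error. Of the named genes and list members, the block in limma added 18 calls and ended 1 (ISL1, adjusted p = 0.052), and of the lists it added the immediate early response (adjusted p = 5.7e-04), which did not pass with an estimated correlation (0.80, or 0.54 with the set as a term).

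Of the 7 lists called, 0 passed with an estimated correlation (1 list at an unadjusted p under 0.05). By fry with the group alone 1 of the 7 passed, the p53 targets, and the other 6 did not (adjusted p = 0.11 to 0.32). Fry then called 3 lists in all, with collagens and matrix and neuronal differentiation. With the set as a term fry gave adjusted p = 0.0036 for p53 targets and for MYC and ribosome biogenesis and 0.020 for integrated stress. S phase had 0.021, hypoxia 0.027, G2 and mitosis 0.033 and ribosomal proteins 0.090. Lists that camera did not call passed too, such as polycomb complexes (0.020). Camera with the set as a term and an estimated correlation did not call the 7 lists (adjusted p = 0.54 to 0.63). Leaving out 1 library gave 6 to 10 lists. Of 12 lists that differed between the sets, 7 lists differed with an estimated correlation. The chromosomes called were 1 without the genes of the runs and 4 to 11 when 1 library was left out, with 11 without GD2-low replicate 1 and 8 without GD2-high replicate 3.

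The reversed values belonged to genes and lists that were not called in the reported comparison, and the cause was not tested. CORO1A reversed with edgeR under TMM and with glmTreat (0.0097), RLE (0.0087) and library totals (0.0046), with DESeq2 (0.013) and in replicates 3 and 4 only (0.30, where it passed at adjusted p = 0.018), and ranged from -0.14 to 0.082 when 1 library was left out. In replicates 1 and 2 only CD44 (0.38), H1-2 (0.14), H2BC5 (0.12) and the lists of noradrenergic products (-8.7e-04), TGF-beta response (0.0086), heat shock (-0.055), unfolded protein response (0.13), histones (0.50), retinoic acid response (-0.021) and lysosome (-0.029) reversed. In replicates 3 and 4 only these were TH (0.081), CLDN5 (-0.14), H4C8 (-0.11), adrenergic regulators (0.026), cholesterol synthesis (0.12) and retinoic acid response (0.023). Without the genes of the runs, ganglioside synthesis (-0.054) and polycomb (-0.0012) reversed, and ganglioside synthesis also with fry (0.078). Retinoic acid response reversed with library totals (-0.0055) and with the block and the set as a term (-0.0019 each), and histones without a filter (-0.13), in the direction of the test where the median kept its sign. When 1 library was left out, CLDN5 ranged from -0.067 to 0.27 and the lists of retinoic acid response from 0.016 to 0.091, histones from -0.42 to 0.15 and unfolded protein response from -0.13 to -0.051.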

Other observations

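A gene whose value stood out was chosen after it was seen. FOS, an immediate early gene, had a value of -3.12 ± 1.97 that did not pass the test (adjusted p = 0.37), and it differed between the sets of replicates, at -0.998 and -5.23 (adjusted p of the difference 6.0e-12). Over all genes, 3899 differed between the sets of replicates by limma, and the effect of the fraction differed between the sets for 12 of 33 lists, or 7 with an estimated correlation.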
